A study of Mus musculus with 6 samples.

How the data were processed

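Total RNA of B16F10 cells was extracted with Trizol and sequencing libraries were made from 2 µg with a SMARTer mRNA-seq kit, per the labels' protocols. The libraries were grouped by culture medium from their titles, 3 in DMEM and 3 in RPMI-1640. The labels also give a replicate number from 1 to 3 in each group. Nothing says what the remaining codes in the titles mean, among them HG for the DMEM libraries, L3 for DMEM replicate 3 and L2 for the others. Before the replicate number, every DMEM title has a 3 and every RPMI-1640 title a 1. This code runs wholly with the medium, so anything it marks cannot be told apart from the medium. The deposited table holds FPKM, fragments scaled to gene length in kilobases and to the mapped fragments of the library, computed by the authors for each library and not pooled; the unit is named by the table itself. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here, so reads of overlapping genes could have been split in unknown ways. FPKM sums per library ran from 431400 to 499334 and were lower in RPMI-1640. The table has 21878 genes, of which 6308 were 0 in all libraries, 12 had symbols turned into dates and 428 were LOC identifiers.

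Whole reads were recovered from the table. The FPKM of a gene in a library is a whole multiple of what a read is worth, so ratios between libraries gave reads per gene, the relative depth and, from 987 genes with a single annotated transcript, of which 113 agreed on the commonest factor, the library totals. All 10624 tested genes came out whole within 0.001. At 1 FPKM a gene of median length (2859 bases) had between 106 and 133 reads. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom from 4.65 to 27.9), so no library was a copy of another. Since the deposited unit is FPKM, counts were not the main input.

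Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2(FPKM + 1), with the medium as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested; an adjusted p under 0.05 was called. Values were used as deposited, with no further scaling. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists with at least 5 tested members; camera with an estimated correlation and fry were alternatives. The 31 lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined; 38 genes stand in more than 1 list. The rule names Slc16a3, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 FPKM, no overlap between the media and a symbol that is not provisional, and up to 3 called members with the largest change of each biology list, or 1 of each other list. It gave 88 genes, and some results are not reported here. Counts over a list alone were adjusted over that list's tested members. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for tables, permutation and Fisher tests and figures.

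Positions, GC content and shared sequence were taken from GENCODE release M21, an annotation of GRCm38, by gene symbol; 10288 of the 10624 tested symbols (96.8%) had a GC value. For each gene the share of 32-base words of its longest transcript that occur in transcripts of other genes was counted, and 331 tested genes shared over 50%. Values of such genes are uncertain, and those named in the results are listed there. For the length and GC trend, the deviations of each library from the gene means were fitted with natural splines of 5 degrees of freedom on log2 length and on GC content, and the fit was subtracted. The gene length used was that implied by the FPKM steps.

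Replicate numbers were checked for pairing by a rule on correlations. Deviations from the group means correlated across genes at 0.151, 0.150 and 0.382 between libraries with the same number, all over 0.1, and each library correlated best with its own number on the deposited values, so the numbers were taken to pair the libraries. The pairing comes from the data alone. With the length and GC trend removed the same correlations were 0.0467, 0.0280 and 0.132. There DMEM replicate 1 and RPMI-1640 replicate 2 correlated at 0.0708, better than either did with its own number. The rule was then not met, so the pairing is uncertain.

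The steps were tested on simulated data. The simulation used the spread of the 10624 tested genes in the comparison of RPMI-1640 with DMEM. In it limma recovered 29.4% of genes changed by 0.25 on the log2 scale, 80.3% of those changed by 0.5 and 100% of those changed by 1. It called 5 unchanged genes. Only 68, 66 and 66 genes were changed by these amounts, while 76.0% of genes were called in the data. Benjamini-Hochberg adjustment is stricter where few genes change, so these shares do not give the sensitivity of the comparison itself. When a length and GC trend was added over 10288 genes, 7978 unchanged genes were called before its removal and 4 after. The added trend was linear in log2 length and GC content, which the removal fits, so its removal was bound to succeed. The simulated changes were placed at random. The simulation thus cannot show whether removal also takes away true differences that run with length or GC content. With the glycolysis list moved, camera called it and also 2 unmoved lists, hypoxia response, which shares members with it, and MHC class I antigen presentation. In 40 simulations with no change 3.5% of lists had a camera p under 0.05. The simulated genes varied independently, while the estimated correlation within the glycolysis list was 0.379 in the data. This rate therefore does not show how often camera at the preset correlation calls lists of correlated genes. The alternatives were other pseudocounts, filters and scalings, other eBayes settings, a minimum fold change, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were removal of the length and GC trend, with and without the block and with an estimated correlation, limma voom on the recovered reads, and a test of only genes with under 10% shared words.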

Results

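Gene expression was profiled by RNA sequencing in B16F10, an established mouse melanoma cell line, kept in either of 2 culture media. There were 3 libraries from cells in DMEM and 3 from cells in RPMI-1640. The titles of the DMEM libraries also carry the code HG, which the labels do not explain, and the labels give no glucose level for either medium. Both are widely used basal media, and each was supplemented with fetal bovine serum. The deposited values are FPKM for 21878 gene symbols. Library totals recovered from the steps of the values were 44821000, 36960000 and 46404000 reads for DMEM and 38989000, 45361000 and 37828000 reads for RPMI-1640, rounded. The tested set held 10624 genes with a mean of at least 1 FPKM. Values below are means ± SD over the 3 libraries of a medium, and log2 fold changes are RPMI-1640 minus DMEM on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say that the 3 libraries of a medium came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

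The comparison asks how the transcriptome of these cells differs between the media. Glycolysis, hypoxia response, cholesterol synthesis, interferon response and MHC class I genes were lower in RPMI-1640, and amino acid response, DNA replication and mitosis genes were higher. In limma, 8078 of the 10624 genes (76.0%) passed an adjusted p of 0.05, 4316 of them higher and 3762 lower in RPMI-1640. With the values scaled to a common total, which raised the median log2 fold change from 0.033 to 0.19, the split was 5472 higher and 2654 lower. Most changes were small, with a median absolute log2 fold change of 0.45 among the genes called, and 678 called genes (374 higher, 304 lower) changed by at least 1 on the log2 scale. The values of the media did not overlap for 8390 genes (79.0%), where chance gives 10%. Of the 25 gene lists with at least 5 tested members, 16 differed by camera with a preset correlation of 0.01, 12 of them lower and 4 higher in RPMI-1640. With an estimated correlation only the cholesterol synthesis call held. The pentose phosphate and unfolded protein response lists lost their calls at estimates of -0.063 and -0.0067, below the preset. The other lists that lost a call had estimates above 0.01. A lost call in this setting therefore need not reflect correlated genes. Genes named below as exceptions to the direction of their list or for a move with the trend removed, and Slc16a1, Cd274, B2m, Aldoa, Pgk1, Tpi1, Eno1, Col1a2 and Acsl1, were chosen after their values were seen.

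The fold change followed gene length and base composition. Across the 10288 tested genes with both values, Spearman's correlation of the log2 fold change was 0.467 with length and -0.488 with GC content; genes are not independent replicates, and no p is given. With the genes in 10 bins of equal size, the bin of the shortest genes had a median log2 fold change of -0.33 and that of the longest 0.55, while the bin with the lowest GC content had 0.39 and that with the highest -0.37. Among DMEM libraries, the deviation of replicate 3 from its group mean correlated at -0.483 with length and 0.671 with GC content, so the same axis also separated libraries within a medium. DMEM replicate 2 lay the other way (0.571 and -0.441), and RPMI-1640 replicate 3 the same way (-0.271 and 0.437). DMEM replicate 3 alone has the code L3 in its title, where the others have L2, and the labels explain neither. The axis was therefore not particular to the library with L3. Without DMEM replicate 3, 8011 genes passed in limma. With this trend removed from each library, 7615 of 10288 genes passed in limma; 5496 of the calls were shared with the same sign, and 1229 genes called on the deposited values changed sign. Medians with the trend removed are therefore given for the lists. Of 403 called list members with a value there, each counted once, 334 kept their sign and call, 30 kept the sign without passing, 24 changed sign without passing and 15 passed with the other sign. Of these, Atp5j, Chac1, Cox8a, Ftl1, H2-Q4, Idh3g, Mpc2 and Ndufa8 went from lower to higher, and Acaca, Canx, Herc6, Kdm3a, Myo5a, Slc7a11 and Tyr from higher to lower. Values of genes that share over 50% of their sequence words with other genes are uncertain. Among the genes named these are Acaca, Acat2, Eno1, Ftl1, Gapdh, Hist1h3c, Oas1a, Pgk1, S100a4, Trf and Zbed6.

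**Figure D1:**
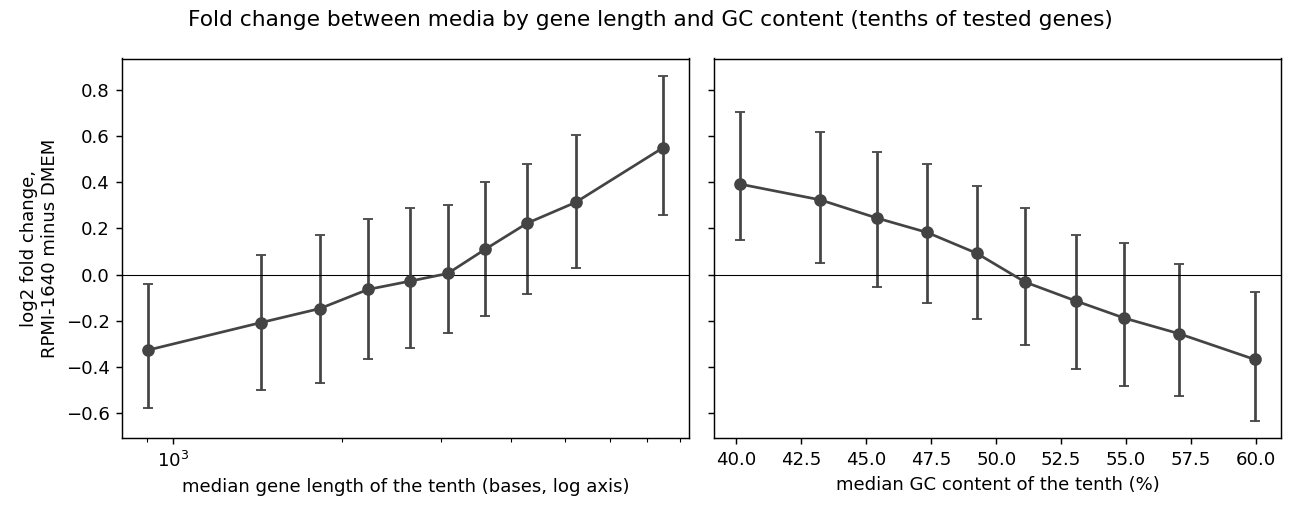
Median log2 fold change (RPMI-1640 minus DMEM, log2 of FPKM + 1) of tested genes in 10 bins of equal size by gene length (left, log axis, bases) and by GC content (right, percent); vertical bars span the quartiles of the genes in a bin. The median climbs from -0.33 in the shortest genes to 0.55 in the longest genes and drops from 0.39 to -0.37 with GC content.

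Slc16a3, the lactate exporter named in the title of the series, was lower in RPMI-1640. It stood at 91.5, 93.2 and 103 FPKM in the DMEM libraries and at 22.4, 23.2 and 22.9 FPKM in the RPMI-1640 libraries, 4.20-fold higher in DMEM (95.9 ± 6.25 against 22.8 ± 0.401). The log2 fold change was -2.02 (SE 0.054, limma adjusted p = 4.39e-10) and rested on 2199 to 12139 reads per library. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it can give. The gene (ENSMUSG00000025161.16) lies on the plus strand of chromosome 11, from 120948480 to 120960868 in GRCm38, and none of the 32-base words of its transcript occurred in transcripts of other genes.

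Other genes of lactate and monocarboxylate handling moved less. Of 9 tested members, 6 were lower, 2 higher and 1 did not pass, with the same counts adjusted over the list alone. Bsg, the chaperone of these transporters, was 2.30-fold higher in DMEM (log2 fold change -1.20, or -0.80 with the trend removed). Slc16a8, a transporter at low level, and Emb were higher in RPMI-1640 (log2 fold changes 0.76 and 0.33); that of Slc16a8 was 1.49 with a pseudocount of 0.01, 1.15 with values scaled to a common total and 1.25 with the trend removed, and that of Emb was 0.15 with the trend removed. Slc16a1, the other common lactate transporter, was at 27.5 FPKM in DMEM and 25.9 in RPMI-1640 and did not pass, although its log2 fold change of -0.083 became -0.50 and passed with the trend removed. Mpc2, of the mitochondrial pyruvate carrier, was lower (-0.17) but turned to 0.20 and passed as higher with the trend removed, where 6 members were lower and 3 higher. The list did not pass as a set (median -0.36, or -0.43 with the trend removed; camera adjusted p = 0.0508). It lay close to the threshold: camera gave an adjusted p of 0.0376 with the replicate number as a block, 0.0497 with a pseudocount of 0.01, 0.0220 with a mean of at least 5 FPKM, 0.0280 with values scaled to a common total and 0.0396 with voom. It also passed without DMEM replicate 2 (0.0431), DMEM replicate 3 (0.0420), RPMI-1640 replicate 1 (0.0481) or RPMI-1640 replicate 3 (0.0497), but not with an estimated correlation (adjusted p = 0.273) or with the trend removed (0.101).

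**Figure D2:**
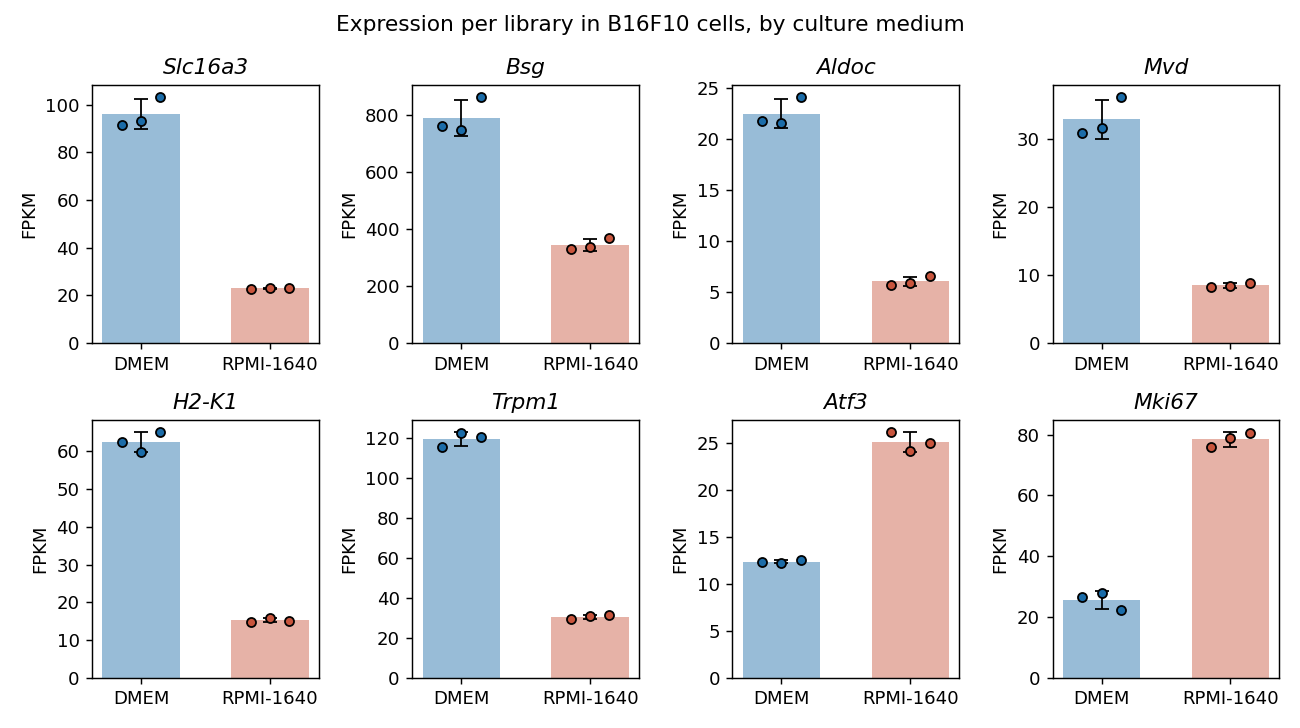
FPKM of 8 genes in the 3 DMEM and 3 RPMI-1640 libraries; bars are means, error bars SD and points single libraries, and each vertical axis starts at 0. Slc16a3, Bsg, Aldoc, Mvd, H2-K1 and Trpm1 were lower and Atf3 and Mki67 higher in RPMI-1640, with no overlap between the media.

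Glycolysis genes were lower in RPMI-1640 along nearly the whole pathway. Of 19 members, 18 were lower and 1 was higher, with the same counts adjusted over the list alone. Aldoc, an aldolase, was at 22.5 ± 1.41 FPKM in DMEM and 6.03 ± 0.435 in RPMI-1640 (log2 fold change -1.74), and Pfkl, the liver-type phosphofructokinase, at 124 ± 8.11 and 49.9 ± 2.30 (-1.29). The exception was Pfkfb3, which makes the activator of phosphofructokinase, with a log2 fold change of 0.90. The list median was -0.84, or -0.87 with the trend removed (camera adjusted p = 1.93e-07; adjusted p = 0.178 with an estimated correlation).

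Gapdh had the lowest log2 fold change of the named genes, -4.59 (SE 0.39, limma adjusted p = 1.06e-06), but its level is uncertain. It stood at 113, 315 and 530 FPKM in the DMEM libraries and at 9.63, 11.3 and 9.51 FPKM in the RPMI-1640 libraries, far below Aldoa, Pgk1, Tpi1 and Eno1 in every library. The 32-base words of its transcript were shared with other genes for 84.0% of its length, and Gapdh has many processed pseudogenes. The gene (ENSMUSG00000057666.18) lies on the minus strand of chromosome 6, from 125161715 to 125166467.

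**Figure D3:**
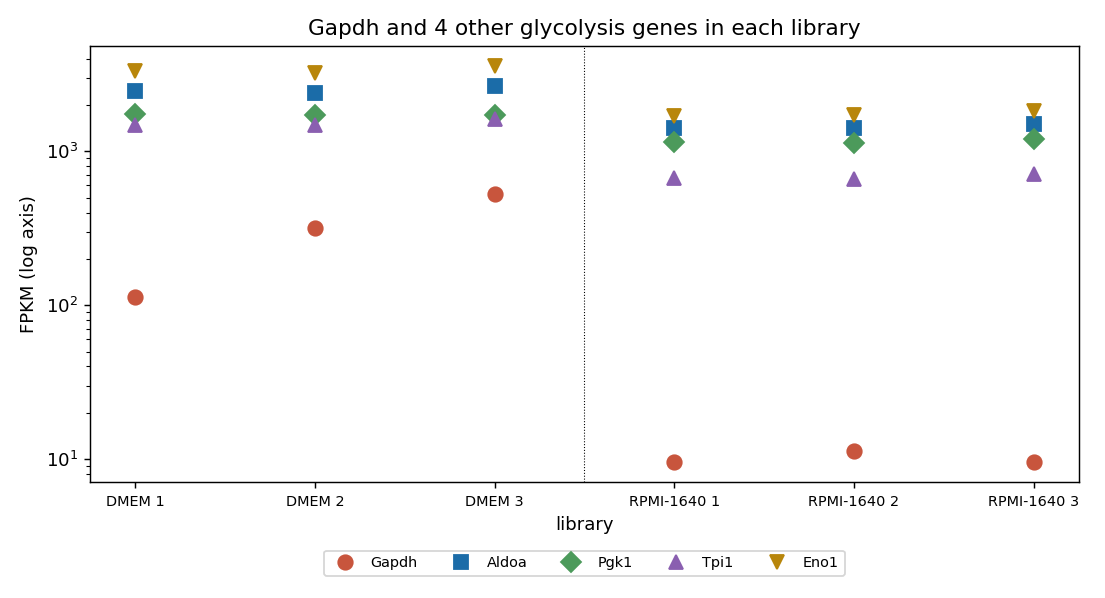
FPKM (log axis) of Gapdh, Aldoa, Pgk1, Tpi1 and Eno1 in each of the 6 libraries, 1 point per gene and library. Gapdh ranges from 113 to 530 in DMEM and from 9.51 to 11.3 in RPMI-1640, while Aldoa, Pgk1, Tpi1 and Eno1 stay close between the libraries of a medium.

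Hypoxia response genes, many of them targets of hypoxia-inducible factors, were also mostly lower in RPMI-1640. Of 24 tested members, 18 were lower, 4 higher and 2 did not pass, also adjusted over the list alone. Bnip3, a mitophagy receptor, fell from 141 ± 7.47 FPKM in DMEM to 28.2 ± 1.29 in RPMI-1640 (log2 fold change -2.28), and Egln1, an oxygen-sensing prolyl hydroxylase, and Higd1a had log2 fold changes of -1.62 and -1.43. Of the words of Bnip3, 26.3% were shared with other genes. Vegfa, Pfkfb3, Slc2a3 and Kdm3a were higher. With the trend removed 19 were lower and 3 higher, and Kdm3a changed sign, to -0.23. The list median was -0.83, or -0.71 with the trend removed (camera adjusted p = 5.13e-05; adjusted p = 0.138 with an estimated correlation).

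Genes of the oxidative branches of sugar metabolism showed smaller differences. In the pentose phosphate pathway 5 of 9 members were lower, 1 was higher (Prps1) and 3 did not pass, also adjusted over the list alone. The lower ones included Pgd (log2 fold change -0.92) and G6pdx (-0.65), both NADPH-producing enzymes, and Pgls (-1.02, or -0.41 with the trend removed). The list had a camera adjusted p of 0.0349 (median -0.39, or -0.27 with the trend removed), with adjusted p = 0.178 with an estimated correlation, and 0.0566 among genes with under 10% shared words. In oxidative phosphorylation 28 of 37 members were lower, 1 was higher (Ndufs1) and 8 did not pass, also adjusted over the list alone. Ndufa1 (-0.75), Cox4i1 (-0.74, or -0.43 after quantile normalization and -0.22 with the trend removed) and Cox5a (-0.60, or -0.39) were the most changed. The list median of -0.40 shrank to -0.11 with the trend removed, where 19 members were lower and 5 higher; the camera adjusted p was 5.96e-06 on the deposited values and 0.0157 with the trend removed, and adjusted p = 0.272 with an estimated correlation. The tricarboxylic acid cycle list did not pass as a set (10 of 22 lower, 3 higher, 9 not passing, also over the list alone; camera adjusted p = 0.0833; median -0.10, or -0.035 with the trend removed), with Pcx, pyruvate carboxylase, the most changed at -0.73 (-0.40 with the trend removed). The targets of the glucose sensors MondoA and ChREBP went both ways (3 of 8 higher, 5 lower, also adjusted over the list alone; camera adjusted p = 0.269; median -0.49, or -0.37 with the trend removed). Txnip, an inhibitor of glucose uptake, was 1.81-fold higher in RPMI-1640, while Tkfc and Gpd1 had log2 fold changes of -0.77 and -0.75.

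Cholesterol synthesis genes moved together, with 24 of 25 members lower in RPMI-1640, 0 higher and 1 not passing. Adjusted over the list alone, 25 were lower. Mvd, mevalonate diphosphate decarboxylase, fell from 33.0 ± 2.85 to 8.49 ± 0.348 FPKM (log2 fold change -1.84), Tm7sf2, a sterol reductase, from 17.6 ± 0.426 to 5.53 ± 0.517 (-1.51) and Acat2, a thiolase, from 40.8 ± 1.92 to 16.3 ± 2.45 (-1.28, uncertain, since 50.2% of its words were shared). The list median was -0.75, or -0.90 with the trend removed (camera adjusted p = 1.28e-09, and 0.0463 with an estimated correlation). Fatty acid synthesis was less uniform, with 10 of 17 members lower, 3 higher and 4 not passing, also adjusted over the list alone. Acss2 (-0.81), Elovl1 (-0.80) and Fads2 (-0.69, or -0.37 with the trend removed) were lower, and Acaca, Elovl6 and Acsl4 higher, of which Acaca and Acsl4 changed sign with the trend removed (-0.23 and -0.074) and Acsl4 and Elovl6 did not pass there. In all, 12 were then lower and 1 higher. This list had a camera adjusted p of 0.0283 (median -0.30, or -0.37 with the trend removed) and of 0.106 after quantile normalization (adjusted p = 0.252 with an estimated correlation).

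Genes of the amino acid response driven by ATF4 were higher in RPMI-1640. Of 38 tested members, 31 were higher, 2 lower (Chac1 and Ddit4) and 5 did not pass; 32 were higher and 2 lower adjusted over the list alone. Removal of the trend gave 34 higher and 1 lower. Chac1 turned to 0.28 and passed as higher and Slc7a11, the cystine transporter, went from 0.49 to -0.33 and passed as lower, while Ddit4 (0.091) and Vldlr (from 0.56 to -0.14) changed sign and did not pass. Atf3, a stress-induced transcription factor, rose 2.04-fold (12.3 ± 0.159 to 25.1 ± 1.03 FPKM), Slc7a1, a cationic amino acid transporter, 1.96-fold and Xpot, the tRNA exporter, 1.96-fold. With the trend removed, the log2 fold change of Slc7a1 went from 0.96 to 0.60 and that of Xpot from 0.95 to 0.48. The list median was 0.44, or 0.45 with the trend removed (camera adjusted p = 2.64e-06; adjusted p = 0.138 with an estimated correlation). One-carbon and folate genes did not pass as a set (12 of 20 higher, 2 lower, 6 not passing, also over the list alone; camera adjusted p = 0.0924; median 0.27). Tcn2, a carrier of vitamin B12, and Cbs, of transsulfuration, were the 2 lower members (log2 fold changes -1.42 and -1.06). The fold of Cbs depended on the pseudocount, with -1.83 at 0.01. The set passed after quantile normalization (camera adjusted p = 0.0371), without the filter (0.0457) and with a mean of at least 5 FPKM (0.0457), but not with an estimated correlation (adjusted p = 0.296) or with the trend removed (0.234), where 9 were higher and 4 lower and the median was 0.077.

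Stress and metal lists were mixed. In the unfolded protein response 13 of 21 members were lower, 3 higher and 5 did not pass, also adjusted over the list alone. Sdf2l1, an endoplasmic reticulum chaperone component, was 2.04-fold higher in DMEM (log2 fold change -0.56 with the trend removed), while the sensors Atf6 (0.95, or 0.36) and Ern1 (0.94) were higher, as was Sel1l (0.75, or 0.31). The camera adjusted p was 0.0208 (median -0.31, or -0.29 with the trend removed), and 0.126 after quantile normalization (adjusted p = 0.138 with an estimated correlation). The NRF2 antioxidant list did not pass (13 of 27 lower, 7 higher, 7 not passing, also over the list alone; camera adjusted p = 0.105; median -0.12, or -0.17 with the trend removed), although the glutathione transferases Gsta4 (-1.83) and Gstm1 (-1.06, 33.6% of its words shared) and Srxn1 (-0.96) were lower. Iron handling did not pass either (8 of 14 lower, 4 higher, 2 not passing, also over the list alone; camera adjusted p = 0.106). It passed with values scaled to a common total (0.0486) but not with an estimated correlation (adjusted p = 0.240) or with the trend removed (0.0700), where the median went from -0.45 to -0.26. Steap3, a ferrireductase, was lower (-1.07), as were the transferrin receptor Tfrc (-0.78, or -1.28 with the trend removed) and transferrin itself, Trf (-0.74, uncertain, with 80.6% of its words shared and 63.5% of it overlapping Gm20425).

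Proliferation genes were higher in RPMI-1640. In the DNA replication list 23 of 28 members were higher, 2 lower (Ccne1 and Fen1, the latter not passing with the trend removed) and 3 did not pass, also adjusted over the list alone. Pola1, a polymerase subunit, rose 2.30-fold, Mcm4, of the replicative helicase, 1.90-fold and Rrm2, of ribonucleotide reductase, 1.70-fold. Removal of the trend left 21 higher and 2 lower, and Rrm1, called as higher, was among those that changed sign (-0.053) and did not pass. In the mitosis list 24 of 27 members were higher, 1 lower (Ccnf) and 2 did not pass, also adjusted over the list alone; with the trend removed 24 were higher and 1 lower, and Bub1 went from 0.42 to -0.026 and did not pass. Mki67, the antigen used to mark cycling cells, rose from 25.6 ± 3.07 to 78.5 ± 2.43 FPKM, and the kinetochore genes Cenpe and Cenpf rose 3.29-fold and 2.98-fold. These are long transcripts, and with the trend removed the log2 fold changes of Pola1, Cenpe, Mki67 and Cenpf went from 1.13, 1.59, 1.58 and 1.45 to 0.60, 0.89, 0.89 and 0.60. The list medians were 0.35 for DNA replication and 0.52 for mitosis, or 0.34 and 0.44 with the trend removed, with camera adjusted p of 0.000345 and 2.64e-06. Each list had adjusted p = 0.138 with an estimated correlation. Among p53 targets 12 of 17 members were lower, 3 higher (Mdm2, Rrm2b and Ddb2) and 2 did not pass, also adjusted over the list alone; Mdm2 went to -0.027 and did not pass with the trend removed, where 13 were lower and 3 higher. Cdkn1a, the p21 cell cycle inhibitor, fell from 224 ± 8.21 to 91.1 ± 3.91 FPKM (-1.29), and Phlda3 and Ccng1 had log2 fold changes of -1.41 (-0.90 with the trend removed) and -1.16. The camera adjusted p for p53 targets was 0.00396, with a median of -0.42 with and without the trend (adjusted p = 0.138 with an estimated correlation).

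Antigen presentation and interferon response genes were lower in RPMI-1640. In the MHC class I list 14 of 16 tested members were lower, 1 higher (Canx) and 1 did not pass, also adjusted over the list alone. There were again 14 lower and 1 higher with the trend removed, but Canx turned to -0.13 and passed as lower, and H2-Q4, with 42.3% of its words shared, went from -0.16 to 0.16 and passed as higher. H2-K1, a classical class I heavy chain, fell from 62.5 ± 2.66 to 15.2 ± 0.514 FPKM (log2 fold change -1.97; 22.2% of its words were shared), and the peptide transporter Tap1 from 5.39 ± 0.507 to 1.79 ± 0.175 (-1.20). The nonclassical H2-T23 was at 3.14 and 0.314 FPKM (-1.66, and -3.33 with a pseudocount of 0.01; 47.4% of its words were shared). B2m, the invariant light chain, was the most abundant of the chains and differed little (376 ± 18.7 and 334 ± 8.74 FPKM, log2 fold change -0.17, but 0.045 after quantile normalization). The list median was -0.68, or -0.57 with the trend removed (camera adjusted p = 5.27e-05; adjusted p = 0.138 with an estimated correlation). Of 26 tested interferon response genes, 19 were lower, 3 higher (Ifit2, Cxcl10 and Herc6, the last at -0.34 with the trend removed) and 4 did not pass, also adjusted over the list alone; with the trend removed 23 were lower and 2 higher. Ifi27 (-1.32), Oas1a (-1.29, uncertain, with 68.2% of its words shared) and Rsad2 (-1.16) were the most changed. The median was -0.67, or -0.62 with the trend removed (camera adjusted p = 7.08e-05; adjusted p = 0.138 with an estimated correlation).

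Among immune ligands and secreted factors, lower values in RPMI-1640 were more frequent than higher ones. Of the 22 checkpoint ligands listed, 10 were tested, of which 6 were lower, 2 higher (Pvr, and Cd47, which did not pass with the trend removed) and 2 did not pass, also adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.106; median -0.32, or -0.16 with the trend removed). Lgals3, a galectin, fell from 106 ± 5.63 to 14.8 ± 0.771 FPKM (-2.76), Lgals9 had a log2 fold change of -0.87, and Nectin2 one of -0.50 (-0.20 with the trend removed). Removal of the trend left 5 lower and 1 higher, and Tnfsf9 went from -0.31 to 0.025 and did not pass. Cd274, which encodes the PD-1 ligand, was at 2.23 and 2.51 FPKM and did not pass, except as higher with values scaled to a common total (log2 fold change 0.28). Of 16 tested chemokines and cytokines 10 were lower, 4 higher (Cxcl10, Csf1, Vegfa, and Vegfc, which did not pass with the trend removed) and 2 did not pass, also adjusted over the list alone. Spp1, osteopontin, fell from 10.7 ± 0.154 to 0.570 ± 0.0726 FPKM (-2.89), and Tgfb1 and Il18 had log2 fold changes of -1.16 (-0.75 with the trend removed) and -0.94 (-1.46 with a pseudocount of 0.01). The camera adjusted p was 0.0322 (adjusted p = 0.178 with an estimated correlation). It was 0.286 with the trend removed, where 7 were lower and 3 higher and the median went from -0.43 to -0.060, 0.158 without the filter, 0.132 with the stricter filter and 0.137 among genes with under 10% shared words.

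Melanocyte pigmentation genes were more often lower than higher in RPMI-1640. Of 21 tested members, 13 were lower, 4 higher (Mitf, Tyr, Myo5a and Pax3) and 4 did not pass, also adjusted over the list alone; Tyr and Myo5a changed sign, to -0.38 and -0.22, with the trend removed, and Pax3 did not pass there, where 16 were lower and 1 higher. Cited1, a transcriptional coactivator, fell from 88.6 ± 8.18 to 19.1 ± 1.23 FPKM (-2.15), Trpm1, melastatin, from 119 ± 3.56 to 30.5 ± 1.05 (-1.93) and Oca2 from 21.6 ± 0.740 to 10.2 ± 0.498 (-1.01). The camera adjusted p was 0.00228 (median -0.31, or -0.38 with the trend removed), and 0.182 after quantile normalization (adjusted p = 0.178 with an estimated correlation).

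Extracellular matrix and adhesion genes were more often higher in RPMI-1640, with 19 of 29 higher, 8 lower and 2 not passing; 19 were higher and 9 lower adjusted over the list alone. Itga4, an integrin chain, rose from 4.70 ± 1.32 to 21.1 ± 1.52 FPKM (1.98, or 1.12 with the trend removed) and Cyr61, a secreted matricellular protein, from 29.8 ± 1.05 to 99.2 ± 1.65 (1.70), whereas Loxl2, a lysyl oxidase, fell from 8.31 ± 0.892 to 2.20 ± 0.331 (-1.54; 47.0% of its words were shared). The camera adjusted p was 0.0231, and 0.0450 with the trend removed, where the median went from 0.41 to 0.21. It was 0.0571 with the trend removed and the replicate number as a block, and 0.0636 without the filter (adjusted p = 0.240 with an estimated correlation).

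**Figure D4:**
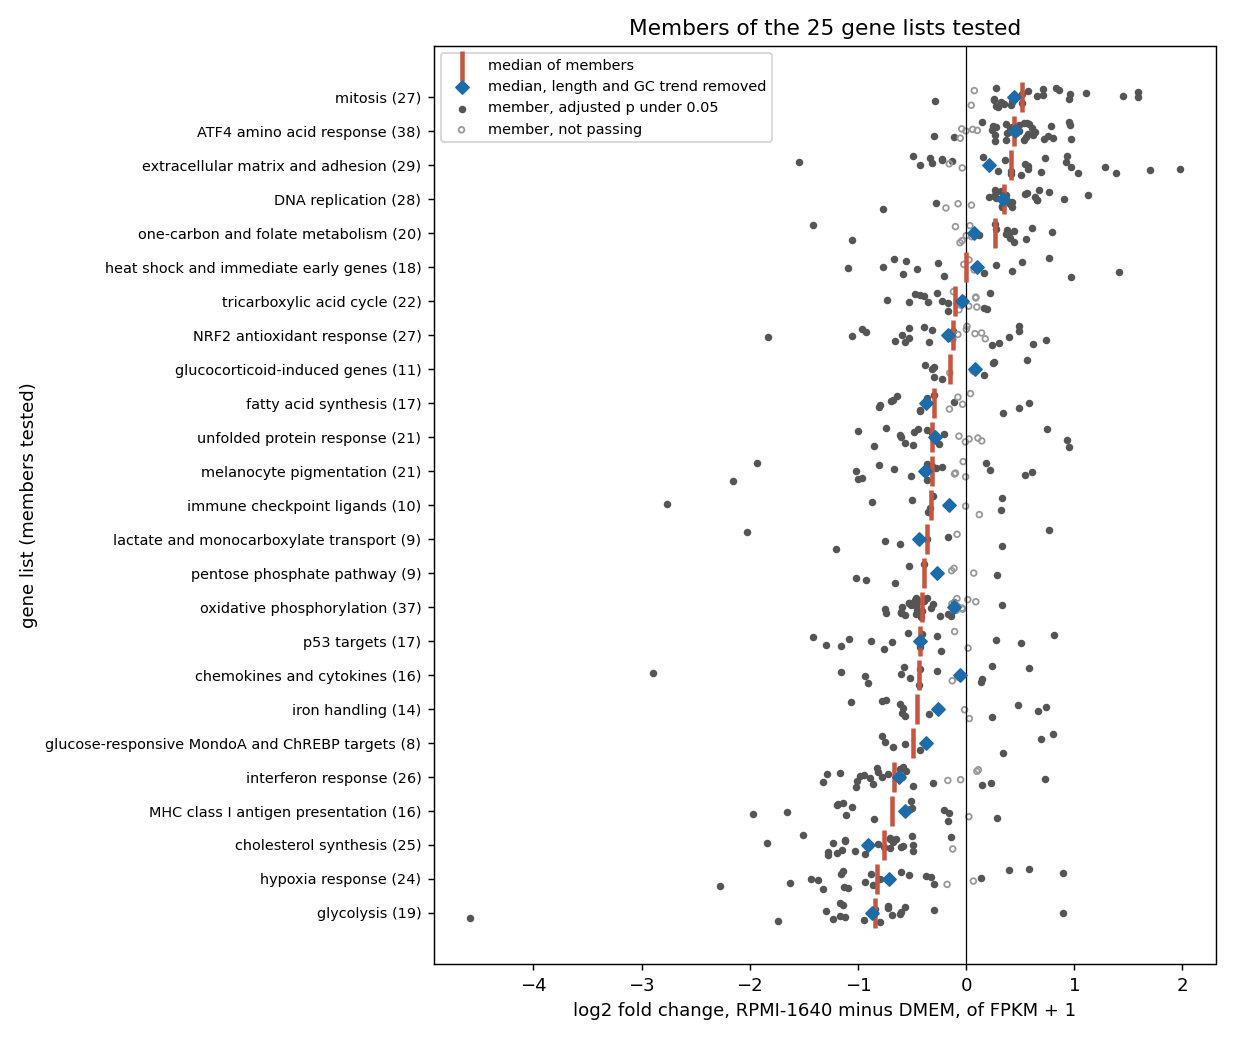
Log2 fold change (RPMI-1640 minus DMEM, log2 of FPKM + 1) of the tested members of the 25 lists tested, 1 point per gene, filled where the limma adjusted p was under 0.05; red bars are list medians and blue diamonds medians with the length and GC trend removed. Glycolysis (median -0.84) and cholesterol synthesis (-0.75) lie to the left of 0 and mitosis (0.52) to the right, and the oxidative phosphorylation median moves from -0.40 to -0.11.

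Small changes among the genes named after their values were seen depended on the library and the setting. Of 50 such genes called in limma, the following did not pass when a library was left out, given with their log2 fold changes there. Without DMEM replicate 1 they were B2m (-0.13), Chac1 (-0.13), H2-Q4 (-0.15), Kdm3a (0.15), Mpc2 (-0.15) and Tnfsf9 (-0.24), without DMEM replicate 2 Chac1 (-0.12) and Csf1 (0.13) and without DMEM replicate 3 Chac1 (-0.10), Csf1 (0.11), Herc6 (0.16) and Kdm3a (0.090). Leaving out RPMI-1640 replicate 1 gave Chac1 (-0.089), Herc6 (0.19), Kdm3a (0.16), Mpc2 (-0.15), Tnfsf9 (-0.21) and Tyr (0.16), replicate 2 B2m (-0.15), Chac1 (-0.11), Csf1 (0.12), Cxcl10 (0.14), H2-Q4 (-0.12), Herc6 (0.22), Idh3g (-0.14), Kdm3a (0.14), Tnfsf9 (-0.28) and Tyr (0.18) and replicate 3 Csf1 (0.14), H2-Q4 (-0.15) and Kdm3a (0.13). After quantile normalization Atp5j, B2m, Chac1, Csf1, Ftl1, Herc6, Idh3g, Kdm3a, Mpc2 and Vegfc did not pass, with the sign changed for Atp5j (0.0033) and B2m (0.045). The log2 fold change of Ftl1 there was -3.7e-15, since the method gives a gene of the same rank in all libraries the same value. Its lost call was therefore fixed by the method. With values scaled to a common total Atp5j, B2m, Ccnf, Chac1, H2-Q4, Idh3g, Mpc2 and Tnfsf9 did not pass, with the sign changed for Chac1 (0.047), and with median ratio scaling neither did Csf1, Cxcl10 and Kdm3a. Ftl1, Herc6, Kdm3a and Tnfsf9 did not pass without the filter, nor did Chac1 and Kdm3a with eBayes without a trend or Chac1 and Csf1 with voom.

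The largest changes of single genes lay partly outside these lists. Espn, an actin-bundling protein, fell from 33.5 ± 0.979 to 4.85 ± 0.0508 FPKM (log2 fold change -2.56), Mgll, monoacylglycerol lipase, from 91.3 ± 1.21 to 16.2 ± 0.166 (-2.42) and Cck, cholecystokinin, from 10.0 ± 0.106 to 1.71 ± 0.162 (-2.03). Hes1, a transcriptional repressor downstream of Notch (chromosome 16, from 30064384 to 30067796), rose from 9.47 ± 0.380 to 47.4 ± 1.09 FPKM (2.21, limma adjusted p = 2.30e-10). Prpf39 (2.10), Paxbp1 (2.06), Ccnl1 (2.01) and Rsrp1 (1.81) were also among the 10 most raised. Zeb2, a transcription factor, rose 3.68-fold (1.82, or 1.13 with the trend removed), and Acot2, an acyl-CoA thioesterase, 3.86-fold, with 36.8% of its words shared. The values of Zbed6 (2.30) and Hist1h3c (2.22) are uncertain, since Zbed6 lies inside Gm38394 and shared all of its words, and Hist1h3c, a histone gene, shared 54.8%.

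Markers of other cell types were mostly low or at 0. Of 20 leukocyte markers 12 were listed at 0 in all 6 libraries, as were 4 of 13 fibroblast, 3 of 10 endothelial, 7 of 15 adipocyte and 8 of 12 keratinocyte markers. A count of 0 allows up to 3 reads in a library, counting error only. In these 5 lists, 4, 4, 1, 3 and 1 members were tested, too few for a set test. In the same order, 0, 1, 0, 1 and 0 members were higher in RPMI-1640, and 2, 2, 1, 1 and 1 lower, with the same counts adjusted over each list alone. Cd74 (-1.20, or -0.79 with the trend removed), S100a4 (-1.60, uncertain, and -3.41 with a pseudocount of 0.01; 58.0% of its words shared, and 51.7% of it overlapping Gm42674), Lipe (-0.73, or -1.11 with that pseudocount) and Perp (-1.08, or -1.73) were lower in RPMI-1640, all from under 6 FPKM in DMEM. The higher members were Col1a2 (1.38, or 2.43 with a pseudocount of 0.01) and Acsl1 (0.33, or 0.17 with the trend removed). Egfl7, at 34.4 FPKM in DMEM, had a log2 fold change of -0.41, of -0.25 with values scaled to a common total and of 0.054 with the trend removed, where it did not pass. The labels carry a treatment text that describes adipogenic induction with dexamethasone, at odds with a melanoma line compared between media. Among glucocorticoid-induced genes 4 of 11 were higher, 5 lower and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.672; median -0.15, or 0.082 with the trend removed); Tsc22d3 had a log2 fold change of 0.57. Of the heat shock and immediate early genes 7 of 18 were higher, 8 lower and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.769, direction down, with a median of 0.0029, or 0.10 with the trend removed, and a mean of 0.0014); Egr1 rose from 2.12 ± 0.243 to 7.27 ± 0.170 FPKM. The 13 mitochondrially encoded transcripts of the fixed list were not analysed here.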

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

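The removal of the length and GC trend (alone, with the block or with an estimated correlation), voom on recovered reads and the test of genes with few shared words were chosen after seeing the data. Slc16a3 kept its direction and its call in all 20 alternatives, with log2 fold changes from -2.07 to -1.77 and from -2.05 to -1.97 when each library was left out. The count of changed genes stayed within 1.5 times of 8078 (7454 to 8011 without each library; 3994 to 4289 higher and 3460 to 3772 lower), except that 678 genes passed when a log2 fold change of at least 1 was also asked for, which is stricter by construction. It was 8968 without the filter and 6555 with a mean of at least 5 FPKM, where more or fewer genes were tested, 8085 with voom, 6908 of 8975 genes with under 10% shared words, and 7615 with the trend removed. With the replicate block it was 8432; on the deposited values the block added the call for lactate and monocarboxylate transport, which other settings also added, and changed no other call of a list or of a gene named by the rule. With the trend removed as well it was 7713, and the block ended the call for extracellular matrix and adhesion. The number of lists called was 16 and ranged from 14 to 18 over the scalings, filters, pseudocounts and fits (16 to 17 without each library). It was 1 with an estimated correlation, 2 (cholesterol synthesis and mitosis) with that and the trend removed, and 24 with fry, which does not compare a list with other genes. Camera takes no robust option, so that alternative gave no list value.

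Among the lists and the genes named by the rule, directions turned for 3, and the cause was not tested; exceptions named after their values were seen, such as Tyr and Kdm3a, are not counted here. Egfl7 went to 0.054 with the trend removed, and to 0.054 with the block too. For glucocorticoid-induced genes the adjusted p was 0.400 with the trend removed, 0.317 with the block too, 0.464 with an estimated correlation too and 0.862 in fry, all in the higher direction. For heat shock and immediate early genes the same alternatives gave 0.360, 0.383, 0.414 and 0.00622, and genes with few shared words gave 0.756. Among genes named by the rule the other 1705 comparisons with an alternative kept direction and call. Depth limits little at these totals, since a gene at 1 FPKM and median length had at least 106 reads, but 3 libraries per medium bound every estimate of spread.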

Other observations

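Some gene families were looked at after their values were seen, and no test is given for them, since they were picked for the pattern they show. Of 61 splicing factor genes (Srsf, Rbm, Prpf, Luc7l, Clk, Srrm and Tra2 genes), 47 passed in limma as higher in RPMI-1640, 8 as lower and 6 did not pass. Their median log2 fold change was 0.48, or 0.29 with the length and GC trend removed, and it was above 0 under all 3 scalings. Of 18 subunits of the V-ATPase, which acidifies lysosomes and melanosomes, 14 passed as lower, 1 as higher and 3 did not pass (median -0.33). The median stayed below 0 under all 3 scalings, but shrank to -0.20 after quantile normalization and to -0.17 with values scaled to a common total. With the trend removed 16 were lower and 0 higher, with a median of -0.36. Genes of the actin cytoskeleton and SRF targets were higher in 10 of 14 cases and lower in 3, with a median of 0.41, or 0.31 with the trend removed, and above 0 under all 3 scalings. Other families depended more on the processing. Cytosolic ribosomal proteins were lower in 65 of 80 cases and higher in 4 (median -0.33), but with the trend removed 34 were lower and 20 higher (median -0.050), and the median was -0.034 after quantile normalization, -0.17 with values scaled to a common total and -0.37 with median ratio scaling. Zinc finger Zfp genes went from 162 of 283 higher and 38 lower to 101 higher and 81 lower with the trend removed, and their median from 0.26 to 0.0042; it was 0.19, 0.45 and 0.23 under the same scalings. Mitochondrial ribosomal proteins, proteasome subunits and tubulins had medians of -0.18, -0.055 and -0.19, and of 0.042, 0.097 and 0.12 with the trend removed; that of proteasome subunits was also above 0 after quantile normalization (0.12) and scaling to a common total (0.11). Kinesins and Notch pathway genes had medians of 0.50 and 0.61, or 0.30 and 0.28 with the trend removed.

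Genes often used as references for quantitative PCR were not all level between the media. Of 19 such genes, chosen after the data were examined, 4 were higher, 8 lower and 7 did not pass. The share called was below the 76.0% called over all tested genes, so a change was not particular to reference genes. Actb was 1.71-fold and Ywhaz 1.76-fold higher in RPMI-1640, and Rplp0 was 1.85-fold, Tfrc 1.74-fold and Pgk1 1.48-fold higher in DMEM, with these directions kept under the 3 scalings. After quantile normalization the log2 fold change of Pgk1 went from -0.57 to -0.15 and that of Rplp0 from -0.88 to -0.45, and that of Tfrc went from -0.78 to -1.28 with the trend removed. The values of Rplp0, Pgk1 and Eef1a1, which share over 50% of their words with other genes, are uncertain. Eef1a1 (6685 ± 157 and 6391 ± 238 FPKM) and Hsp90ab1 (1073 ± 14.6 and 1039 ± 16.5 FPKM) did not pass, although Hsp90ab1 passed as higher after quantile normalization and both passed as higher in RPMI-1640 with values scaled to a common total.

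The tests of other splits, of Gapdh against the glycolysis list and of shared words over unstable genes were chosen after their results were seen. The tests of trend removal, of scaling and of the shared words of Gapdh were set before their own results were seen, but after the patterns and the length and GC trend had been. Most tested genes passed between the media, 8078 of 10624. A general length and GC trend as the whole source is argued against, since 7615 genes passed with it removed. Of these, 5496 were also called on the deposited values with the same sign, but 1229 called genes changed sign. Library scaling as the whole source is argued against too, since at least 8077 passed under each of 3 scalings. Calls shared with the same sign numbered 7360 after quantile normalization, 6970 with values scaled to a common total and 7807 with median ratio scaling. The counts of genes passing hide this turnover, and single calls can still depend on the trend or the scaling. Only 1 of the 10 splits of the 6 libraries gave as many genes, the real one. The highest of the other splits called 0 in limma, with at most 30 genes at an unadjusted p under 0.05. The 3 others that part all same-numbered libraries also called 0. Each other split mixes the media within its groups, so a difference between media adds to the spread and keeps calls low. The 0 calls therefore do not measure what chance gives, and 10 splits are too few to give a share under 0.05. A difference between cultures or library preparations that runs with the medium stays open, as does the medium itself.

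Gapdh had a log2 fold change of -4.59, while the next lowest glycolysis gene, Aldoc, had -1.74. Gapdh lay 2.85 below the lowest other member of the glycolysis list, with an SE of 0.39. Since Gapdh was picked for its low value, this gap restates the pattern. It cannot decide whether a shared fall of the list makes up part of the difference. Reads shared with near-identical copies are a candidate explanation, since 84.0% of the words of Gapdh occur in other genes. Of 15 genes with a mean of at least 20 FPKM and a coefficient of variation over 0.25 in either medium, 80.0% had over 20% shared words, against 11.9% of 4113 others (Fisher's exact test, two-sided, p = 3.06e-09). The 15 include Gapdh itself and related genes such as Rpl17, Rpl7a, Rps27 and Rps29. They are therefore not independent units, and the p is only descriptive. Most genes with over 20% shared words did not vary so much, 491 against 12 that did. The comparison concerns the spread between replicates and does not test the difference between the media. How reads were assigned among copies is not given, so the part of the difference that reflects the medium stays open.

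The length and GC trend was set against the shared movement of 7 lists. With it removed, the medians were -0.87 for glycolysis, -0.71 for hypoxia response, -0.90 for cholesterol synthesis, 0.45 for the ATF4 amino acid response, 0.44 for mitosis and -0.57 for MHC class I antigen presentation, each with its sign, more than 50% of its size and its camera call at the preset correlation kept, which argues against the trend as the whole source for these 6. With the trend removed, glycolysis, hypoxia response, ATF4 and MHC class I did not pass with an estimated correlation (camera adjusted p = 0.164, 0.104, 0.0646 and 0.0657), while cholesterol synthesis and mitosis did (0.0398 and 0.0399). For oxidative phosphorylation the median went from -0.40 to -0.11 with the call kept, and trend and medium cannot be told apart there, since the trend runs with the medium. A response to medium composition in the first 6 is a hypothesis found and tested on the same data, and an untested difference in culture density or RNA handling stays open.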
